A study of Mus musculus with 8 samples.

How the data were processed

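RNA from the colonic mucosa of 8 male wild-type C57BL/6J mice was sequenced, 2 animals in each of 4 groups, sampled on day 7. The control and DSS model groups received saline enemas, and 2 other DSS groups received Kuiyangling at 10 g/kg or mesalazine at 50 mg/kg by enema, each in a volume of 0.2 ml, and the DSS groups drank 3% DSS. Per the labels' protocols, RNA was extracted with the mirVana kit, samples with an RNA integrity number of at least 7 were used, and libraries were made with a TruSeq stranded mRNA kit. The deposited counts are whole numbers of reads per gene, which the authors made with pipelines naming Trimmomatic and HISAT2 per the submitters' processing notes, without version or role. The genome build, annotation, read counter and strand setting were not given in the sources used here, so no coordinates are reported. The deposited FPKM values are the authors' counts divided by 1 length per gene and by the totals of the deposited counts, a relation checked on the values. Column headers of the tables carried the group and the replicate, and the mesalazine group was spelled in different ways in its 2 columns, which were taken as replicates 1 and 2 by their number.

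Totals ran from 15560946 to 17843715 counts, with 15217 to 15689 genes detected per library. The tables held 17353 genes. With edgeR 4.0.16 in R 4.3.3, genes passing filterByExpr by group (13381) were scaled by TMM and tested by quasi-likelihood F tests in 1 fit of all 8 libraries with a mean per group. The common biological coefficient of variation was 0.287 and the prior degrees of freedom 6.02. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold limit. The 6 comparisons were each pair of the 4 groups. CPM are counts scaled to library sizes adjusted by TMM, given as mean ± SD over the 2 animals. Log2 CPM per library used a prior count of 2. Folds against a group with 0 counts are bounds computed against a floor of 3 counts over the group, and a group with 1 to 3 counts gives a ratio with its exact (binomial) 95% counting interval.

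The 30 gene lists, the comparisons, the tests, the rule for naming genes and the alternatives, except where stated, were set before the data were examined. Lists were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison, and again with the correlation estimated per list and with fry. For each list, the members called over all genes and the members called when adjusted over the list alone were counted. Named genes were, per comparison, the 6 called genes with the highest and the 6 with the lowest log2 change among genes with a mean of at least 5 CPM, no overlap between the libraries of the groups and an established symbol, then up to 2 called members per list with the smallest p (otherwise the member with the smallest p, by its value), then a fixed panel of 16 genes, of which 15 were in the table. Genes of the first parts of the rule were left out of the text where space was short, and some are not reported here. Mpo was not analysed here. GO and KEGG annotations came with the deposited tables: 1339 genes had no GO term and 10391 no pathway. Terms with 10 to 500 tested genes were tested by one-sided Fisher tests for the called genes of each direction, adjusted over 3385 GO terms or 318 KEGG terms.

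Because the DSS model libraries enter several comparisons, reversal of DSS changes and overlap of the treatments were set against 50 simulations of all genes from the fitted spread, in which the 33 genes called between the DSS model and controls differed between these groups and no gene differed between the treatments and the model. Genes were drawn independently, with the 33 genes at their observed group means. This design of the simulations was chosen after a first form of it had been seen. The covariance of log2 changes was also reduced by an estimate of the part that the shared libraries give, the mean variance within all 4 groups divided by the number of model libraries. After these results were seen, the covariances were also computed with a different model library in each change.

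Methods were tested on simulated counts with the means and library sizes of these libraries. For the DSS model against control, 8%, 78%, 96% and 98% of 50 genes each were recovered at 2-fold, 4-fold, 8-fold and 16-fold changes, with 10 false calls among 13208 genes. For Kuiyangling against the DSS model the shares were 4%, 76%, 96% and 96%, with 9 false calls among 13195. In each of these checks 200 genes were changed together, which makes the adjusted threshold easier to pass than when few genes change. In the measured libraries Cxcl2, at a log2 change of -2.87 with Kuiyangling against the DSS model, was not called. The shares therefore do not show that large changes were absent where no gene was called. Camera recovered 20 of 20 lists of 20 genes raised 1.5-fold and called 1 of 180 unchanged lists, in 13196 genes. These lists were random genes drawn independently. The check therefore does not give the error rate for lists whose members vary together.

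Alternatives were RLE scaling, no filter on low counts, fits of only the 4 libraries compared, DESeq2 1.42.0 without filterByExpr, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, a replicate block, each library left out in turn, and other call thresholds. After the libraries had been inspected, the fits without control 2 and mesalazine 1 and fits with each library's trend with gene length (loess, span 0.5) removed were added. Gene lengths came from the ratio of the deposited counts and FPKM (median 3310 bases).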

Results

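Polyadenylated RNA of colonic mucosa was sequenced in 8 wild-type male C57BL/6J mice, 2 animals in each of 4 groups, collected on day 7. Control mice received saline enemas. The DSS model group drank water with 3% dextran sulfate sodium, a polymer that injures the colonic epithelium and is widely used to model ulcerative colitis, and received the same saline enemas. A Kuiyangling group drank DSS and received this herbal formula at 10 g/kg by enema. A mesalazine group drank DSS and received mesalazine, an anti-inflammatory drug used in ulcerative colitis, at 50 mg/kg by enema. The question behind the study is whether Kuiyangling lowers inflammation through fewer neutrophil extracellular traps, the webs of chromatin and granule proteins that neutrophils release. Counts were given for 17353 genes, of which 13381 had enough counts to be tested.

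The libraries were of similar depth, with totals between 15560946 and 17843715 counts. Controls held 17843715 and 16065742 counts, the DSS model 16930854 and 15560946, mesalazine 16956439 and 16415984, and Kuiyangling 16015937 and 17622452, each given as replicate 1 and replicate 2. At this depth 3 counts, taken as the floor, correspond to between 0.149 and 0.212 CPM (counts scaled to library size) in a library. A pair of libraries stood apart. Mesalazine replicate 1 had a mean Spearman correlation of 0.940 with the other libraries and control replicate 2 one of 0.945, against 0.963 to 0.974 for the rest. Genes whose symbols begin with Rpl or Rps and a digit, picked by symbol alone, numbered 102 and are here called ribosomal protein genes. They took 12.7% of counts in mesalazine 1, against 3.35% to 6.68% elsewhere. In mesalazine 1, expression relative to the other libraries also went down with gene length (rho = -0.534 across genes, which are not independent replicates). The same rho was -0.433 in DSS model 2 and 0.444 in control 1. Most B cell markers and MHC class II transcripts were higher in control 2 than in control 1, with Cd74 at 1104 against 53.8 CPM, and control 2 had more Hoxb13, a gene of the posterior gut, at 175 against 19.9 CPM. Each comparison below was also run without each library in turn, as planned.

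**Figure D1:**
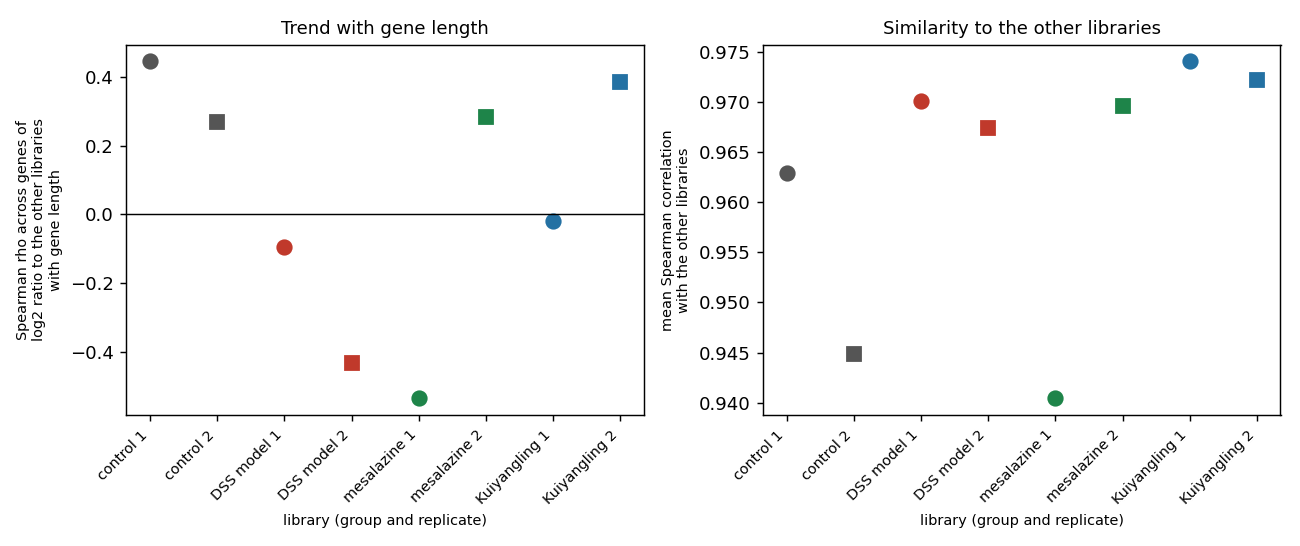
Left, Spearman rho across tested genes between gene length and each library's log2 ratio to the mean of the other libraries. Right, mean Spearman correlation of each library with the others, lowest for mesalazine 1 (0.940) and control 2 (0.945).

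The DSS model was compared with controls to see what the colitis model changed. Genes of neutrophils and of their recruitment rose. S100a9 and S100a8, which form the neutrophil protein calprotectin, stood at 16.0 ± 7.12 and 14.0 ± 6.18 CPM (SD, n = 2), against 0 and 0.0308 ± 0.0436 CPM in controls. S100a9 was at least 192-fold higher (adjusted p = 0.0168) and S100a8, with 1 control count, 505-fold higher (95% counting interval 90.2 to 20001; adjusted p = 0.00611). The neutrophil chemoattractant Cxcl2 rose 205-fold (56.3 to 1699.6; adjusted p = 0.00273), to 11.3 ± 1.74 CPM, and Cxcl5 at least 65.4-fold (adjusted p = 0.00611). Il1b, the inflammasome cytokine, rose by 4.83 on the log2 scale (SE 0.61; adjusted p = 0.0168), to 24.9 ± 15.9 CPM, and Ptgs2, the inducible cyclooxygenase, by 5.35 (SE 0.71; adjusted p = 0.0180).

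The protease genes Mmp13, Mmp10 and Prss22 rose as well. Mmp13, a collagenase, went from 0.896 ± 0.134 to 52.4 ± 45.3 CPM (log2 change 5.85, SE 0.76; adjusted p = 0.0176). Mmp10, stromelysin 2, rose 391-fold from 2 control counts (108 to 3232.5; adjusted p = 0.0218), and the serine protease Prss22 415-fold from 1 (74.0 to 16427; adjusted p = 0.00273). In the epithelium-related lists, Clca4b, of the calcium-activated chloride channel regulator family, rose from 35.3 ± 1.64 to 633 ± 62.7 CPM (4.16, SE 0.39; adjusted p = 0.00273). Il1rl1, the receptor of interleukin 33, rose by 5.29 (SE 0.64; adjusted p = 0.0147) and Plaur, the urokinase receptor, by 2.60 (SE 0.38; adjusted p = 0.0249). Among the 7 genes called lower, Mptx1, a mucosal pentraxin, changed by -8.47 (SE 1.19; adjusted p = 0.0220), from 1142.5 ± 1426 to 3.21 ± 0.622 CPM, and by -5.38 without control 2. Col8a1, a short-chain collagen, changed by -3.88, Tppp3, a tubulin-binding protein, by -3.46, and Ttll6, a tubulin polyglutamylase, by -2.07 (adjusted p = 0.0495, 0.0218 and 0.0472).

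Other genes of the fixed panel did not pass the test. Reg3g, an antimicrobial lectin, stood at 3613 ± 747 against 85.8 ± 40.2 CPM (5.40; adjusted p = 0.0557), Cxcl1 at a log2 change of 4.04 (adjusted p = 0.0603), and Lcn2, a siderophore-binding protein, at 4.51 (0.158). Tnf stood at 12.1 ± 3.06 against 4.29 ± 0.467 CPM (adjusted p = 0.138). Il6 had 36 counts against 2, a ratio of 21.1 (5.44 to 181). The goblet cell mucin Muc2 was at -0.48, the colonocyte anion exchanger Slc26a3 at -1.19 (-0.57 without control 2) and the carbonic anhydrase Car1 at 0.64 (0.16 without control 2). Of the genes closest to trap formation, Padi4, which citrullinates histones, had 3 counts in the model and 1 in controls, and Elane, neutrophil elastase, 1 in each, both at or under the floor. Cxcr2, the receptor of these chemokines, was too low to be tested and had 25 counts against 0, at least 9.79-fold more.

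**Figure D2:**
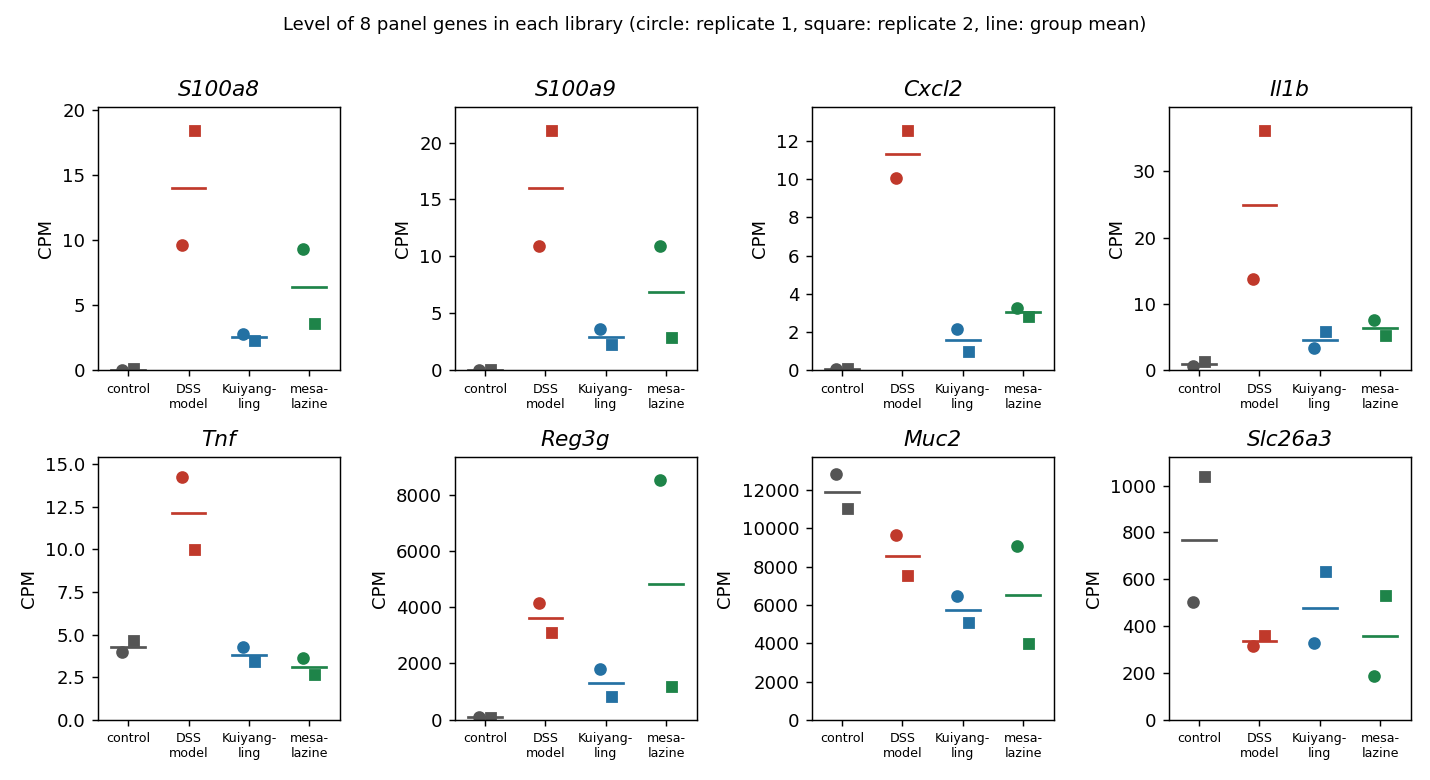
CPM of 8 panel genes in each library, with circles for replicate 1, squares for replicate 2, lines for the group mean and linear axes from 0. S100a8, S100a9, Cxcl2, Il1b and Tnf have their highest group mean in the DSS model, whereas the mesalazine libraries lie far apart for Reg3g (4840 ± 5179 CPM).

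Gene lists of inflammation, wound response and matrix rose. Of 16 neutrophil markers 4 rose, and 12 rose and 1 fell adjusted over the list alone (median log2 change 5.15, or 5.06 with the 3 members at 0 in controls at their bound). Of 12 neutrophil-attracting chemokines and growth factors 3 rose, 5 adjusted over the list alone (median 2.10). Of 15 inflammatory cytokines and mediators 3 rose, 12 adjusted over the list alone (2.87), of 24 epithelial antimicrobial and wound genes 2 rose and 16 adjusted over the list alone (1.45), and of 29 extracellular matrix and remodelling genes 2 rose and 23 adjusted over the list alone (2.03). These 5 lists rose by camera (adjusted p = 2.67e-18, 1.15e-11, 7.10e-19, 1.30e-19 and 9.33e-26). The calls were lost, with adjusted p = 0.121, 0.186, 0.0777, 0.0777 and 0.187 with an estimated correlation.

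The neutrophil extracellular trap components, 19 tested genes of which 2 rose adjusted over the list alone and 0 over all genes, had a median of 0.34 and rose by camera (adjusted p = 0.0154). Adjusted p = 0.620 with an estimated correlation, and without control 1 it was 0.719 with the preset one. The member with the smallest p was Mmp9, a gelatinase of neutrophil granules (4.21, adjusted p = 0.120). Padi4, Elane, Prtn3, Ctsg and Camp had too few counts to be tested. The list test therefore says nothing of these genes.

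Another 8 lists changed. Higher by camera were the oxidative phosphorylation genes (median 0.63, all 25 estimates above 0, for example Cox6c at 1.10), erythroid and skeletal muscle genes (3.11, Hba-a1 at 3.42), monocyte and macrophage markers (0.41; Chil3 had 52 counts against 0, at least 20.4-fold more) and unfolded protein response genes (0.64, with Ern2 at -1.41). Their adjusted p-values were 1.61e-06, 3.56e-06, 0.0207 and 0.0411, and adjusted p = 0.620, 0.296, 0.645 and 0.620 with an estimated correlation. Lower by camera were the intestinal stem cell and Wnt target genes (-0.62, Axin2 at -2.23), smooth muscle genes (-1.27, Actg2 at -2.43), interferon-stimulated genes (-0.80, Oas2 at -1.98) and enteroendocrine and tuft cell genes (-0.54, the tuft cell kinase Dclk1 at -1.81). Their adjusted p-values were 0.000332, 0.00513, 0.00845 and 0.0144, and adjusted p = 0.220, 0.620, 0.762 and 0.348 with an estimated correlation. Members of these 8 lists called over all genes numbered 0. Adjusted over the list alone, 5 erythroid genes rose, and 3 stem cell, 3 enteroendocrine and tuft and 1 smooth muscle gene fell.

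Some of these list calls rested on 1 library. With the preset correlation, the monocyte list lost its call without control 1 (adjusted p = 0.178), the smooth muscle list without control 1 (0.826) or DSS model 1 (0.163), the unfolded protein response list without control 1 (0.129) or DSS model 1 (0.295), the interferon list without control 2 (0.216, its direction turned), and the enteroendocrine and tuft list without DSS model 2 (0.109). With gene length corrected for, the monocyte and unfolded protein response lists were at 0.135.

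The remaining 16 lists did not pass. Median log2 changes were 0.20 for NF-kB and inflammasome genes, with Nlrp3 at 2.93, -0.70 for MHC class II and antigen presentation, -0.88 for T and NK cell markers, -2.24 for B and plasma cell markers, -0.29 for colonocyte absorption and transport, in which Clca4b rose, -0.21 for goblet cell genes, with the goblet cell protein Clca1 at -2.01 (-0.90 without control 2), and 0.08 for tight and adherens junction genes. They were -0.03 for cell cycle genes, -0.82 for enteric neuron and glia genes, 1.24 for endothelial genes (adjusted p = 0.0928), -0.34 for adipocyte genes, 0.51 for squamous epithelium and keratinocyte genes and -0.10 for immediate early genes. Median, mean and test differed in sign for eosinophil and mast cell markers (median -0.69, mean 0.04, test down), PPAR and fatty acid oxidation genes (-0.03, -0.06, up) and xenobiotic metabolism genes (-0.04, 0.09, up).

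In all, edgeR called 33 genes between the DSS model and controls, 26 higher and 7 lower, each by at least 2-fold, and 1987 had an unadjusted p under 0.05, where chance gives 669. The libraries of the groups did not overlap for 53.4% of genes, against 33.3% by chance. By one-sided Fisher tests the higher genes were over-represented in 19 GO terms, led by neutrophil chemotaxis (6 of 26 called genes against 57 of 12765; adjusted p = 4.40e-06), and in 8 KEGG pathways, led by IL-17 signaling (8 of 18 against 73 of 5669; adjusted p = 6.41e-09). The count of 33 depended on single libraries: it was 1 without control 2, 104 without control 1, 8 without DSS model 2, 21 without DSS model 1, 152 without mesalazine 1 and 159 without mesalazine 2, and DESeq2 called 425 (252 higher, 173 lower), among them all 33, and limma on FPKM 16 (12 higher, 4 lower). Of the 16 called genes named above, 15, all but Mptx1, lost the call without control 2 (adjusted p = 0.0616 to 0.257), 9 without DSS model 2 (0.0558 to 0.342), 5 without DSS model 1 (0.0804 to 0.237), 3 without control 1 (0.0503 to 0.0711), and 2 without either Kuiyangling library (0.0626 to 0.0843). Limma on FPKM ended 6 of these calls (0.0649 to 0.175), the fit of only the 4 libraries compared 2 (0.0557 to 0.0659), the replicate block 1 (0.0565) and length correction 1 (0.0796). DESeq2 was run without the filter on low counts, and edgeR without that filter called 487. Without control 2, the estimates of all 16 named genes kept their sign. Il1b was at 5.37, Clca4b at 4.21 and Ptgs2 at 5.23, while Tppp3 was at -2.63 and Mptx1 at -5.38. With 1 control animal left, a lost call need not mean a smaller change. The p-values of single genes rest on the spread between these animals, and the counting intervals and floors cover counting error only. Those of camera with its preset correlation and of the Fisher tests set genes against other genes. They do not measure the spread between animals.

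Kuiyangling was compared with the DSS model to see what the formula changed in injured mucosa. Neutrophil and cytokine genes had lower values in the Kuiyangling animals, but no single gene passed the test. S100a8 stood at 2.51 ± 0.391 against 14.0 ± 6.18 CPM (SD, n = 2; log2 change -2.48, SE 0.56), S100a9 at 2.94 ± 1.004 against 16.0 ± 7.12 (-2.44), and Cxcl2 at 1.55 ± 0.871 against 11.3 ± 1.74 CPM (-2.87, SE 0.47; adjusted p = 0.820). Il1b stood at 4.53 ± 1.67 against 24.9 ± 15.9 CPM (-2.45), Tnf at 3.82 ± 0.634 against 12.1 ± 3.06 (-1.66) and Reg3g at 1308.5 ± 726 against 3613 ± 747 (-1.47). The adjusted p of these genes other than Cxcl2 was 0.996. Cxcr2 had 0 counts against 25, at least 9.53-fold fewer. Padi4 and Elane had 0 counts each in the Kuiyangling animals against 3 and 1, at or under the floor in both groups. Cxcl1 was at -1.81, Il6 at -1.39, Lcn2 at -0.80, Muc2 at -0.58, Slc26a3 at 0.50 (-0.05 without Kuiyangling 2) and Car1 at 0.36.

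As groups, the inflammatory lists fell by camera. The neutrophil markers had a median of -2.31, with 10 of 16 members lower adjusted over the list alone, the inflammatory cytokines -1.32 with 7 of 15, and the neutrophil-attracting chemokines -1.79 with 1 of 12 (adjusted p = 1.24e-20, 1.49e-12 and 4.07e-08). These had adjusted p = 0.135, 0.135 and 0.230 with an estimated correlation. Also lower were epithelial antimicrobial and wound genes (-0.76, Sprr1a at -1.19), interferon-stimulated genes (-0.68, the chemokine Cxcl9 at -2.60), unfolded protein response genes (-0.53, Creld2 at -1.09), oxidative phosphorylation genes (-0.37, Sdhc at -0.47, all 25 estimates below 0) and NF-kB and inflammasome genes (-0.46, the inflammasome sensor Nlrp3 at -2.12). Their adjusted p-values were 2.57e-09, 1.37e-09, 1.09e-06, 3.74e-06 and 3.98e-05, and adjusted p = 0.138, 0.444, 0.201, 0.528 and 0.318 with an estimated correlation. In these 5 lists 0 members were lower adjusted over the list alone.

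As before, Padi4, Elane, Prtn3, Ctsg and Camp were not among the trap components tested. None of the 19 neutrophil extracellular trap components tested was called, even adjusted over the list alone. As a list they fell by camera (median -0.28, Mmp9 at -1.86, adjusted p = 0.0153). They had adjusted p = 0.528 with an estimated correlation, and 0.172 without Kuiyangling 2 with the preset one. The goblet cell genes (-0.34, the secreted protein Retnlb at -1.44), MHC class II and antigen presentation (-0.43, Psmb9 at -1.14), tight and adherens junction genes (-0.17, Cldn8 at -1.32, the 1 member lower adjusted over the list alone) and enteroendocrine and tuft cell genes (-0.14) were lower too (adjusted p = 0.000322, 0.000425, 0.00962 and 0.0133). They had adjusted p = 0.346, 0.580, 0.579 and 0.318 with an estimated correlation.

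Lists of stem cell and stromal genes rose by camera between Kuiyangling and the DSS model. The intestinal stem cell and Wnt target genes had a median of 0.53, with 15 of 17 estimates above 0 and the Wnt regulator Rnf43 at 0.94. The smooth muscle genes had 0.94, with 14 of 14 above 0 and the smooth muscle myosin Myh11 at 2.37. Endothelial genes had 0.99, with 12 of 13 above 0 and the junction protein Pecam1 at 1.44, extracellular matrix genes 0.73, with the collagen cross-linking enzyme Lox at 1.81, and xenobiotic metabolism genes 0.26, with the bilirubin-conjugating enzyme Ugt1a1 at 1.09. The adjusted p-values were 8.54e-07, 4.54e-06, 2.94e-05, 0.00102 and 0.0270, and adjusted p = 0.138, 0.318, 0.284, 0.580 and 0.485 with an estimated correlation.

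The other 12 lists did not pass in this comparison. Their medians were 0.11 for monocyte and macrophage markers, 0.46 for T and NK cell markers, -0.57 for B and plasma cell markers, -0.52 for eosinophil and mast cell markers, 0.22 for colonocyte absorption and transport, 0.31 for enteric neuron and glia genes, -0.24 for squamous genes, -0.05 for PPAR genes and -0.10 for immediate early genes. Median, mean and test differed in sign for cell cycle genes (0.03, -0.07, down), adipocyte genes (0.10, -0.61, down) and erythroid genes (-0.04, 0.03, up).

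Between Kuiyangling and the DSS model edgeR called 0 genes, with 476 at an unadjusted p under 0.05 where chance gives 669. With only the 4 libraries compared in the fit, 1463 genes had an unadjusted p under 0.05. A count under chance in the fit of all 8 libraries therefore does not show that genes were unchanged. DESeq2 called 13 (6 higher, 7 lower, Cxcl2, Il1b and S100a8 among the lower) and limma on FPKM 0. A fit of only the 4 libraries compared called 21, and 28 were called without control 2 and mesalazine 1. The libraries did not overlap for 43.0% of genes, against 33.3% by chance. Leaving out DSS model 1 ended the list calls of goblet cell genes (adjusted p = 0.191), enteroendocrine and tuft genes (0.244), junction genes (0.369) and extracellular matrix genes (0.810). Leaving out Kuiyangling 2 ended those of MHC class II (0.138), enteroendocrine and tuft genes (0.263) and junction genes (0.0507), and the xenobiotic call was lost without DSS model 2 (0.0556) or Kuiyangling 1 (0.214). With gene length corrected for, the enteroendocrine and tuft list was at 0.108.

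Mesalazine, the reference drug, was compared with the DSS model in the same way. The cytokine gene Tnf stood at 3.12 ± 0.695 against 12.1 ± 3.06 CPM (SD, n = 2; log2 change -1.96, SE 0.38; adjusted p = 0.334), Cxcl2 at 3.03 ± 0.321 against 11.3 ± 1.74 (-1.90; adjusted p = 0.503) and Il1b at 6.29 ± 1.71 against 24.9 ± 15.9 (-1.99; adjusted p = 0.523). S100a8 was at 6.42 ± 4.04 CPM (-1.13, or -1.98 without mesalazine 1) and S100a9 at 6.88 ± 5.68 (-1.22, or -2.49 without mesalazine 1). The smallest adjusted p among the named genes was that of Cldn8, a claudin of tight junctions (-1.87; adjusted p = 0.203), followed by Sprr1a, a cornified envelope protein (-1.79; 0.259). Cyp3a13, a drug-metabolizing enzyme, stood at 614 ± 101 against 226 ± 55.8 CPM (1.44; 0.503). None of these genes passed. Reg3g (0.42) and Lcn2 (1.56) turned to -1.63 and -1.43 without mesalazine 1, Muc2 (-0.40) to 0.08 and Slc26a3 (0.09) to -0.86 without mesalazine 2. Cxcl1 was at -1.79, Il6 at -1.19 and Car1 at 0.37. Cxcr2 had 3 counts against 25, a ratio of 0.119 (0.0230 to 0.390), and Padi4 and Elane 0 each.

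Interferon-stimulated genes fell by camera, with a median of -1.70, all 26 estimates below 0, and 8 lower adjusted over the list alone (Irgm1, an interferon-induced GTPase, at -1.67; adjusted p = 1.51e-26). Much of its size came from mesalazine 1: against the control mean the interferon-stimulated genes had medians of -3.52 and -1.73 in the mesalazine libraries and -0.41 and -0.99 in the model, and without mesalazine 1 the adjusted p was 5.54e-06. The inflammatory cytokines fell (-1.49, 15 of 15 estimates below 0, 6 lower adjusted over the list alone), as did neutrophil markers (-1.12, 3 lower, the receptor Csf3r at -2.78), wound genes (-0.66, 4 lower) and neutrophil-attracting chemokines (-1.74, 2 lower), with adjusted p = 1.81e-13, 1.38e-08, 1.38e-08 and 8.94e-07. The first 4 of these 5 lists had adjusted p = 0.233 with an estimated correlation, and the chemokines adjusted p = 0.259 with an estimated correlation. The neutrophil extracellular trap components had a median of -0.12 and did not pass (adjusted p = 0.167).

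Immediate early genes fell (-0.49, 19 of 20 estimates below 0, Egr1 at -1.89), and so did unfolded protein response genes (-0.44, the chaperone Hyou1 at -1.21), MHC class II and antigen presentation (-0.70, the peptide transporter Tap1 at -1.66), junction genes (-0.32, 1 lower adjusted over the list alone), NF-kB genes (-0.24, Bcl3 at -1.51, 1 lower adjusted over the list alone), goblet cell genes (-0.29, the membrane mucin Muc4 at -0.85) and B and plasma cell markers (-0.77, the joining chain Jchain at -1.03). Their adjusted p-values were 4.56e-08, 3.50e-06, 6.34e-06, 6.91e-05, 0.000436, 0.00287 and 0.0235, and adjusted p = 0.285, 0.233, 0.567, 0.424, 0.391, 0.438 and 0.600 with an estimated correlation. Stem cell and Wnt target genes (0.48, Rnf43 at 0.85), T and NK cell markers (0.64, Klrd1 at 1.22) and xenobiotic metabolism genes (0.24, 1 higher adjusted over the list alone) rose, with adjusted p = 6.90e-05, 0.00715 and 0.00848. They had adjusted p = 0.233, 0.600 and 0.424 with an estimated correlation.

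The other 14 lists did not pass, with medians of 0.24 for monocyte and macrophage markers, -0.19 for eosinophil and mast cell markers, 0.09 for colonocyte absorption and transport, -0.33 for enteroendocrine and tuft genes, -0.25 for cell cycle genes, 0.15 for extracellular matrix genes, although Mmp7, matrilysin, was at 2.73 (1.20 without mesalazine 1), 0.21 for smooth muscle genes, -0.12 for neuron and glia genes, 0.43 for endothelial genes, -0.20 for squamous genes, 0.41 for erythroid genes and 0.07 for PPAR genes. Median, mean and test differed in sign for adipocyte genes (0.15, -0.14, up) and oxidative phosphorylation genes (0.05, 0.06, down).

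Between mesalazine and the DSS model edgeR called 0 genes, with 735 at an unadjusted p under 0.05 against 669 by chance, while DESeq2 called 81 (37 higher, 44 lower) and limma on FPKM 0. The fit without control 2 and mesalazine 1 left 1 mesalazine animal, so its calls, given below, cannot be read as genes changed by mesalazine. Libraries did not overlap for 27.7% of genes, against 33.3% by chance. Leaving out mesalazine 2 ended the list calls of chemokines (adjusted p = 0.0834), wound genes (0.106), goblet cell genes (0.729), xenobiotic genes (0.187), unfolded protein response genes (0.0513), T and NK cell markers (0.0820) and B cell markers (0.436). Leaving out mesalazine 1 ended those of junction genes (0.0655), T and NK cell markers (0.149) and B cell markers (0.203). Leaving out DSS model 1 ended those of T and NK cell markers (0.257) and goblet cell genes (0.284), and leaving out DSS model 2 those of B cell markers (0.967) and xenobiotic genes (0.0588). The B cell call was also lost without control 1 (0.103), Kuiyangling 1 (0.116) or Kuiyangling 2 (0.121).

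**Figure D3:**
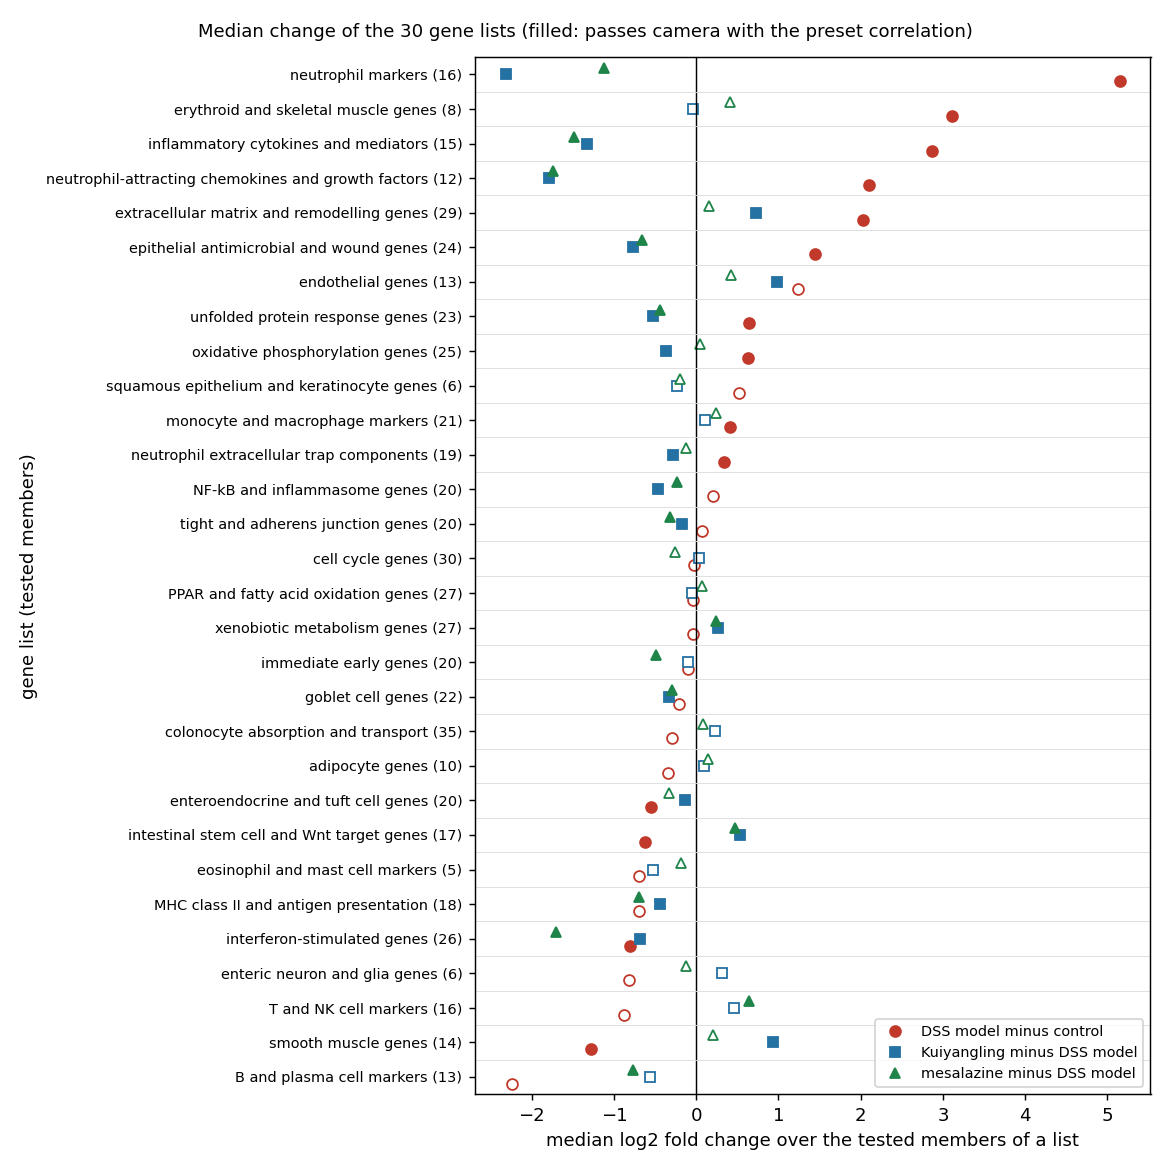
Median log2 fold change over the tested members (number in brackets) of each of the 30 gene lists, for the DSS model against control (circles), Kuiyangling against the DSS model (squares) and mesalazine against the DSS model (triangles). Filled symbols passed camera with the preset correlation; the neutrophil markers lie at 5.15, -2.31 and -1.12.

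Kuiyangling and mesalazine were compared directly, which tests whether their effects against the same DSS animals differed. No single gene passed. S100a8 was lower in the Kuiyangling animals by value (2.51 ± 0.391 against 6.42 ± 4.04 CPM, SD, n = 2; log2 difference -1.35), as was Lcn2 (-2.35), but S100a8 was at -0.51, Lcn2 at 0.61, Reg3g (-1.89) at 0.15 and S100a9 (-1.22) at 0.03 without mesalazine 1. The transcription factor gene Egr1 was at 1.82, Synpo2, a smooth muscle actin-binding protein, at 2.10, the interferon-induced Oasl1 at 1.12, the endothelial cadherin Cdh5 at 1.39, Mmp7 at -1.92 and Ndufb5, of respiratory complex I, at -0.82. Mmp7 was at -0.41 and Ndufb5 at -0.09 without mesalazine 1, and Oasl1 at 0.21 without Kuiyangling 1. Cxcl2 was at -0.97, Il1b at -0.47 and Tnf at 0.30. The signs of Cxcl1 (-0.02), Il6 (-0.20), Muc2 (-0.18), Slc26a3 (0.42) and Car1 (-0.01) turned when single libraries were left out, to 0.50, 0.13, 0.54, -0.16 and 0.20. These came from leaving out mesalazine 1 (Cxcl1, Muc2 and Slc26a3), Kuiyangling 1 (Il6) and Kuiyangling 2 (Car1). Leaving out Kuiyangling 2 also turned Cxcl1 (0.25) and Slc26a3 (-0.13), and leaving out mesalazine 2 turned Car1 (0.06).

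Of the 30 lists 7 differed between the treatments by camera. Interferon-stimulated genes (median 0.83, 23 of 26 above 0), smooth muscle genes (0.78, 13 of 14), extracellular matrix genes (0.59, 21 of 29), endothelial genes (0.48, 12 of 13) and immediate early genes (0.46, 19 of 20) were higher with Kuiyangling, with adjusted p = 1.21e-08, 2.39e-06, 0.000727, 0.00138 and 2.39e-06. Neutrophil markers (-1.10, 15 of 16 below 0) and oxidative phosphorylation genes (-0.42, 24 of 25 below 0) were lower (adjusted p = 0.000517 and 2.39e-06). In this order the 7 lists had adjusted p = 0.919, 0.890, 0.919, 0.890, 0.890, 0.890 and 0.919 with an estimated correlation, and 0 members were called, over all genes or adjusted over the list alone. Mesalazine 1, with its high share of ribosomal protein counts (12.7%) and its trend with gene length, moved with the last list: without it the call was lost with the sign turned (adjusted p = 0.593), and with gene length corrected for it was at 0.198. The interferon and neutrophil calls were also lost without mesalazine 1 (0.329 each), and the matrix, smooth muscle and endothelial calls without mesalazine 2 (0.806 with the sign turned, 0.522 and 0.942). Leaving out Kuiyangling 1 ended the interferon (0.334), matrix (0.0934), endothelial (0.145) and immediate early (0.0934) calls.

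Among lists without a difference by camera, the trap components were at -0.14 (adjusted p = 0.602), and median, mean and test differed in sign for cytokines (-0.15, 0.06, up), chemokines (0.15, -0.04, down) and wound genes (0.17, -0.18, up). EdgeR called 0 genes between the treatments, DESeq2 0 and limma 0, and 254 had an unadjusted p under 0.05 by edgeR where chance gives 669. The mesalazine libraries differed from each other, so this count does not show that the treatments acted alike. Libraries did not overlap for 22.1% of genes, against 33.3% by chance.

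Kuiyangling was also compared with controls, to see what still differed from uninjured mucosa. Genes of the extracellular matrix, of proteins that attract neutrophils and of some proteases were among those that rose. Prss22 rose 308-fold from 1 control count (54.9 to 12218; adjusted p = 0.00742), Mmp10 177-fold from 2 (48.6 to 1465.5; 0.0458), S100a8 90.4-fold from 1 (15.8 to 3612; 0.0429), Cxcl2 27.2-fold from 2 (7.18 to 231; 0.0429), Il33, an epithelial alarmin, 50.4-fold from 2 (13.6 to 422; 0.0313), Cxcl5 at least 46.9-fold (0.0158) and Lox at least 39.1-fold (0.0292). Igfbp5, an insulin-like growth factor binding protein, rose from 0.835 ± 0.571 to 31.9 ± 4.63 CPM (SD, n = 2; log2 change 5.21, SE 0.69; adjusted p = 0.0292). Il1rl1 rose by 4.82, Ptgs2 by 4.61, Clca4b by 3.36 and the fibrillar collagen Col5a2 by 3.51 (adjusted p = 0.0292, 0.0429, 0.0158 and 0.0292). The tuft cell genes Trpm5, a cation channel, and Dclk1 fell, with log2 changes of -3.11 and -2.54 (adjusted p = 0.0313 and 0.0443). Mptx1 changed by -9.04 (-5.95 without control 2), the interferon-induced Ifi27l2a by -3.65, Tppp3 by -3.11 and Sycn, syncollin, by -2.75 (adjusted p = 0.0292, 0.0313, 0.0417 and 0.0429). Not passing were S100a9 (102 counts against 0, at least 34.9-fold more; adjusted p = 0.0567), Reg3g (3.93; 0.0961), Lcn2 (3.71), Il1b (2.37), Cxcl1 (2.23), Il6 (16 counts against 2, a ratio of 8.22 with interval 1.93 to 73.7), Tnf (-0.17), Muc2 (-1.05), Slc26a3 (-0.69) and Car1 (0.999). Without control 2, Slc26a3 was at -0.07 and Car1 at 0.52.

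Against controls, 14 lists changed in the Kuiyangling group, 9 up and 5 down. Extracellular matrix genes rose with the smallest p (median 2.90; 3 members called and 26 of 29 adjusted over the list alone; adjusted p = 3.98e-48). Wound genes (0.63), erythroid genes (3.00), cytokines (1.40), endothelial genes (1.93, 8 of 13 adjusted over the list alone), chemokines (0.80), neutrophil markers (1.87, or 1.85 with 3 members at their bound), xenobiotic metabolism genes (0.42) and monocyte markers (0.52) rose too, with adjusted p = 8.77e-10, 9.38e-09, 2.38e-07, 5.09e-07, 1.17e-05, 1.28e-05, 0.00530 and 0.00537. The 9 lists had adjusted p = 0.212, 0.212, 0.217, 0.217, 0.217, 0.338, 0.338, 0.340 and 0.595 with an estimated correlation. Interferon-stimulated genes (-1.65, 26 of 26 below 0; adjusted p = 4.22e-14), enteroendocrine and tuft genes (-0.23; 2 called and 7 adjusted over the list alone; 3.96e-06), MHC class II (-1.39; 8.01e-06), goblet cell genes (-0.54; 0.000107) and B cell markers (-2.35; 0.00651) fell. These 5 had adjusted p = 0.340, 0.212, 0.595, 0.338 and 0.595 with an estimated correlation. The trap components had a median of -0.01, a mean of 0.22 and an upward test (adjusted p = 0.317), and colonocyte genes a median of -0.28, a mean of -0.17 and an upward test. Control 2, with its B cell and MHC transcripts, decided the B cell and MHC calls: without it they were at 0.222 and 0.0891 with the sign turned, and the xenobiotic list was at 0.202. Without control 1, chemokines were at 0.466 and monocyte markers at 0.212.

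Between Kuiyangling and controls edgeR called 32 genes (25 higher, 7 lower), all by at least 2-fold, with 1376 at an unadjusted p under 0.05. The higher genes were over-represented in 5 GO terms, led by extracellular matrix (6 of 25 called genes against 165 of 12765; adjusted p = 0.00208), and 2 KEGG pathways including IL-17 signaling (adjusted p = 0.00785). Libraries did not overlap for 49.1% of genes, against 33.3% by chance. The count was 1 without control 2, 171 without control 1, 1 without Kuiyangling 1, 13 without Kuiyangling 2, 14 without DSS model 1, 13 without DSS model 2, 62 without mesalazine 1 and 77 without mesalazine 2, and DESeq2 called 341 (205 higher, 136 lower) with all 32 among them, and limma on FPKM 2. Of the 18 called genes named, 17 lost the call without control 2 (adjusted p = 0.0708 to 0.314; Mptx1 kept it), 17 without Kuiyangling 1 (0.101 to 0.303; Prss22 kept it), 11 without Kuiyangling 2 (0.0814 to 0.209), 10 without DSS model 1 (0.0530 to 0.0828), 10 without DSS model 2 (0.0528 to 0.0825) and 4 without control 1 (0.0639 to 0.0759). Limma on FPKM ended 16 of these calls (0.0612 to 0.292), the fit of only the 4 libraries compared 11 (0.0519 to 0.104) and the fit without control 2 and mesalazine 1 ended 2 (0.0587 to 0.0688).

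Mesalazine was compared with controls likewise. Genes of neutrophils, of antimicrobial defence and of some proteases were among those that rose. S100a9 rose at least 78.8-fold (adjusted p = 0.0268), S100a8 224-fold from 1 control count (39.6 to 8875.5; 0.0216), Prss22 283-fold from 1 (50.3 to 11221; 0.00936), Mmp3, stromelysin 1, 452-fold from 1 (80.6 to 17890; 0.0471), Mmp10 206-fold from 2 (56.5 to 1703.6; 0.0312), Cxcl2 54.7-fold from 2 (14.7 to 459; 0.0216), Il33 39.6-fold from 2 (10.5 to 334; 0.0312), Lox at least 36.5-fold (0.0261) and Cxcl5 at least 15.5-fold (0.0270). Reg3b, an antimicrobial lectin, rose from 295 ± 188 to 25450.4 ± 29683 CPM (SD, n = 2; log2 change 6.43, SE 1.12; adjusted p = 0.0414) and Reg3g by 5.82 (0.0312). The acute-phase gene Saa3 rose by 5.05, Il1rl1 by 4.69, Clca4b by 3.62, Slc51a, a subunit of the bile acid exporter, by 2.92 and Cyp2d26 by 2.16 (adjusted p = 0.0268, 0.0261, 0.0105, 0.0312 and 0.0318). Lower genes included Mptx1 (-10.27), Tgm3, a transglutaminase (-9.30), Hoxb13 (-7.76), Nxpe4 (-5.31), Slfn1 (-5.19) and the protease Ctse (-3.96), with adjusted p from 0.0216 to 0.0414. Without control 2, the library with most Hoxb13, these were at -7.19, -6.52, -5.48, -3.58, -3.27 and -2.51. Without mesalazine 1, Reg3b was at 3.92, Reg3g at 3.78 and Saa3 at 3.68. Mmp3 was at 5.89 without mesalazine 1 and 8.60 with it, and Mmp10 at 6.22 and 7.59. The goblet cell genes Clca1 and Muc4 changed by -3.08 and -1.71, the tuft cell gene Trpm5 by -2.63 and Insl5, a colonic L cell hormone, by -3.61 (adjusted p = 0.0365, 0.0430, 0.0329 and 0.0430). Clca1 was at -1.97 without control 2. Not passing were Lcn2 (6.06, or 3.10 without mesalazine 1; adjusted p = 0.0661), Il1b (2.84; 0.0666), Cxcl1 (2.25), Il6 (16 counts against 2, a ratio of 9.31 with interval 2.19 to 83.5), Tnf (-0.46), Muc2 (-0.87), Slc26a3 (-1.10) and Car1 (1.01). Without control 2, Slc26a3 was at -0.49 and Car1 at 0.53.

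Against controls, 18 lists changed in the mesalazine group, 10 up and 8 down. Extracellular matrix genes rose (median 2.16; 6 members called and 25 of 29 adjusted over the list alone; adjusted p = 4.90e-22), as did erythroid genes (3.32; 9.03e-07), neutrophil markers (3.13, or 2.67 with 3 members at their bound; 1.05e-06), wound genes (0.87; 2.62e-05), oxidative phosphorylation genes (0.70; 2.74e-05), cytokines (1.49; 0.000270), chemokines (0.65; 0.000564), xenobiotic genes (0.42; 0.00912), monocyte markers (0.61; 0.0117) and endothelial genes (1.89; 0.0221). These 10 had adjusted p = 0.344, 0.344, 0.344, 0.344, 0.538, 0.344, 0.510, 0.497, 0.538 and 0.538 with an estimated correlation. Interferon-stimulated genes fell (-2.74; 0 called and 24 of 26 adjusted over the list alone; 3.15e-19), with MHC class II (-1.69; 2.62e-05), immediate early genes (-0.81; 0.000173), enteroendocrine and tuft genes (-0.33, 3 called; 0.00190), goblet cell genes (-0.52, 2 called; 0.00491), B cell markers (-2.35; 0.0115), smooth muscle genes (-0.997; 0.0115) and junction genes (-0.32; 0.0149). These 8 had adjusted p = 0.344, 0.538, 0.510, 0.344, 0.510, 0.538, 0.538 and 0.538 with an estimated correlation. Median, mean and test differed in sign for trap components (-0.08, 0.34, up; adjusted p = 0.215), T and NK cell markers (-0.45, -0.24, up) and unfolded protein response genes (0.02, -0.17, down). Without control 2 the MHC class II (0.782) and B cell (0.683) calls were lost with the sign turned, and the junction (0.180) and xenobiotic (0.213) calls were lost. Without control 1 the chemokine (0.605), cytokine (0.0683), monocyte (0.178) and smooth muscle (0.990, sign turned) calls were lost. Leaving out mesalazine 1 ended the monocyte (0.514), junction (0.0925), endothelial (0.400) and oxidative phosphorylation (0.0519) calls. With gene length corrected for, the oxidative phosphorylation (0.246), xenobiotic (0.0972) and monocyte calls were lost. Leaving out mesalazine 2 ended the B cell (0.218), goblet (0.595), enteroendocrine and tuft (0.106), smooth muscle (0.485) and xenobiotic (0.159) calls.

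Between mesalazine and controls edgeR called 90 genes (58 higher, 32 lower), all by at least 2-fold, with 2675 at an unadjusted p under 0.05. The higher genes were over-represented in 19 GO terms, among them antimicrobial humoral response (7 of 58 called genes; adjusted p = 5.09e-06) and extracellular matrix (10 of 58; 5.13e-06), and 3 KEGG pathways led by IL-17 signaling (1.74e-05), and the lower genes in 2 GO terms, of which chloride channel activity held 4 of 32 (0.00186). Libraries did not overlap for 45.7% of genes, against 33.3% by chance. The count was 1 without control 2, 303 without control 1, 4 without mesalazine 1, 2717 without mesalazine 2, 37 without DSS model 1 and 35 without DSS model 2, and DESeq2 called 982 (595 higher, 387 lower) with all 90 among them, and limma on FPKM 30, whereas 23 were called without control 2 and mesalazine 1. Of the 26 called genes named, 25 lost the call without control 2 (adjusted p = 0.0981 to 0.317; Mptx1 kept it), 24 without mesalazine 1 (0.0714 to 0.272; Prss22 and Clca4b kept it), 15 without DSS model 1 (0.0503 to 0.0932), 15 without DSS model 2 (0.0516 to 0.0924), 3 without control 1 (0.0510 to 0.0903) and 1 without either Kuiyangling library (0.0741 and 0.0739). The fit without both control 2 and mesalazine 1 ended 20 of these calls (0.0501 to 0.235), limma on FPKM 15 (0.0504 to 0.185), length correction 6 (0.0510 to 0.0555), and the replicate block (0.0534) and the fit of only the 4 libraries compared (0.0542) 1 each.

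The last comparison asked how far either treatment moved the genes that DSS had changed, and whether both treatments moved the same genes. Of the 33 genes called between the DSS model and controls, 28 (84.8%) had estimates of the opposite sign with Kuiyangling and 29 (87.9%) with mesalazine, but 0 were called in the opposite direction by either. The 26 genes raised in the DSS model, among them S100a8, S100a9, Cxcl2 and Il1b, had a median log2 change of -0.99 with Kuiyangling and -1.20 with mesalazine. The 7 lowered genes were at 0.72 and 0.09, against 0.22 and 0.17 in the simulations described next. Because the DSS model libraries enter both sides, opposite signs arise without any effect: 50 simulations with unchanged treatments gave 54.7% and 52.7% opposite signs and medians of -0.01 and -0.02. The simulations took the observed means of the 33 genes as true, so they largely leave out the selection of these genes in the same model libraries. They also drew genes independently and changed no other gene. The gap between observed and simulated shares and medians therefore cannot tell reversal from selection. The shares and medians over the genes called in each fit depended on single libraries. Without control 1 the shares were 57.7% with Kuiyangling and 55.8% with mesalazine, without mesalazine 2 the share was 43.4% with mesalazine, and without control 2 the only called gene had the same sign in both. The medians for Kuiyangling were -0.30 without control 1 and -0.58 without Kuiyangling 2, and those for mesalazine -0.62 without control 1, -0.75 without DSS model 2 and -0.26 without mesalazine 2. DESeq2 called 5 genes in opposite directions with Kuiyangling (Cxcl2, Acod1, Il1b, Mfsd2a and S100a8; Acod1 and Mfsd2a were named after their values were seen) and 17 with mesalazine, counts for which no simulated value was made. The covariance of the DSS and treatment changes was -0.162 with Kuiyangling, against -0.110 in the simulations, a difference of -0.0521, and -0.0713 against -0.110 with mesalazine, a difference of 0.0384. The correlations, -0.434 and -0.175, were both weaker than in every simulation (means -0.453 and -0.450). The part given by the shared libraries was estimated as -0.116 from the variance within all 4 groups. It was -0.0761 when control 2 and mesalazine 1 were left out. The spread in the simulations came from all groups too, so neither baseline is that of the model libraries alone. Less this estimate the covariance was -0.0466 and 0.0444, and these changed sign without DSS model 2 (0.0451) or Kuiyangling 2 (0.0195), and without mesalazine 1 (-0.125) or control 2 (-0.00984). With gene length corrected for, the covariance was -0.117 with Kuiyangling and -0.0802 with mesalazine, against an estimated shared part of -0.101. The size of these differences is therefore uncertain. The split of the model libraries given below needs no such estimate, but it was not corrected for gene length.

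Kuiyangling and mesalazine shared 0 called genes by edgeR, with 0 called in either, and 252 genes had an unadjusted p under 0.05 in both in the same direction, against 139 in the simulations. DESeq2 gave 9 shared genes, again without a simulated value. Signs were the same for 67.4% of genes, against 66.7% simulated, and the covariance was 0.167 against 0.110, a difference of 0.0571. The correlation was 0.644 against 0.502. These simulated values rest on genes drawn independently and on the spread of all groups, so the differences from them are uncertain in size. Giving each change its own DSS model library, a split chosen after these results were seen, left no shared library. With model 1 in the DSS change and model 2 in the treatment change the covariance was -0.137 for Kuiyangling and -0.0681 for mesalazine, and with the libraries exchanged -0.0174 and 0.0959. Between the treatments it was 0.104 with model 1 on the side of Kuiyangling (59.3% same signs) and 0.0598 with model 2 (47.9%).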

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

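All tests of the difference between the treatments were planned, and the tests that remove the gene length trend or leave out control 2 and mesalazine 1 were chosen after the libraries had been inspected.

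Tested against each other by camera, the effects of Kuiyangling and mesalazine differed in 7 of the 30 lists. The median log2 difference, Kuiyangling minus mesalazine, was -1.10 for neutrophil markers, 0.83 for interferon-stimulated genes, 0.59 for extracellular matrix genes, 0.78 for smooth muscle genes, 0.48 for endothelial genes, -0.42 for oxidative phosphorylation genes and 0.46 for immediate early genes. None of the 7 passed with an estimated correlation (adjusted p = 0.890 to 0.919). Each was lost when 1 library was left out. Without mesalazine 1 the neutrophil (0.329), interferon (0.329) and oxidative phosphorylation (0.593) calls were lost, without mesalazine 2 the matrix (0.806), smooth muscle (0.522) and endothelial (0.942) calls, and without Kuiyangling 1 the interferon (0.334), matrix (0.0934), endothelial (0.145) and immediate early (0.0934) calls.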

How the results depend on the processing

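The fits without control 2 and mesalazine 1 and the fits corrected for gene length were chosen only after the libraries had been seen, and the split of the model libraries after the results. Leaving out control 2 and mesalazine 1 leaves 1 animal in each of these groups and takes away the libraries furthest from the rest. A higher count of calls in that fit therefore does not show more change. The cause of the shifts below was not tested.

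Counts of called genes are given in the order DSS model against control, Kuiyangling against model, mesalazine against model, Kuiyangling against mesalazine, Kuiyangling against control and mesalazine against control. With no filter on low counts they were 487 (254 higher, 233 lower), 11, 104, 3, 451 (240 higher, 211 lower) and 1090 (614 higher, 476 lower). DESeq2, also run without this filter, called 425, 13, 81, 0, 341 and 982, and limma on FPKM 16, 0, 0, 0, 2 and 30, where the median of all genes moved to -0.13, 0.13 and -0.16 for DSS model against control, Kuiyangling against mesalazine and mesalazine against control. With a replicate block, which assumes that equal replicate numbers pair animals, they were 50, 0, 0, 0, 65 and 132, although replicate numbers did not pair the libraries (correlations -0.311 to 0.162). Fits of only the 4 libraries compared called 44, 21, 0, 0, 19 and 315, and without both libraries that stand apart 194, 28, 81, 0, 85 and 23 were called. Unadjusted p under 0.05 with a 2-fold change gave 1210, 330, 481, 183, 1033 and 1776. RLE gave 33, 0, 0, 0, 33 and 89, and length correction 36, 0, 0, 0, 47 and 67. Called genes changed at least 2-fold, so that limit altered nothing. Leaving out 1 library, where the lone sample of a group is assumed to vary like the other groups, gave 1 to 159 genes for the DSS model, 1 to 171 for Kuiyangling and 1 to 2717 for mesalazine against control, and 0 in the treatment comparisons by edgeR. Removal of immunoglobulin and mitochondrial genes was not run, since 0 genes in the table matched.

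An estimated correlation left 0 lists in each of the 6 comparisons, and fry called 3, 0, 0, 0, 0 and 0, or 15, 0, 2, 0, 10 and 9 by its mixed test, which ignores direction. Without 1 library 14 to 20, 16 to 20, 12 to 18, 4 to 11, 14 to 19 and 13 to 20 lists were called, and without both libraries 11 for Kuiyangling against mesalazine. Lists that turned direction had these adjusted p over the fits without 1 library, and then without both: interferon genes in the DSS model 2.24e-07 to 0.216 and 0.269; oxidative phosphorylation between treatments 5.39e-09 to 0.593 and 0.611; MHC class II 1.19e-27 to 0.0891 and 0.140 for Kuiyangling and 2.38e-25 to 0.782 and 0.504 for mesalazine against control; B cell markers 6.80e-17 to 0.222 and 0.281, and 2.54e-14 to 0.683 and 0.845. Matrix genes between treatments (7.68e-19 to 0.806) and smooth muscle genes for mesalazine against control (2.49e-08 to 0.990) turned without 1 library. Of 1204 list values 946 kept direction and side of the threshold, 244 no longer passed and 14 turned.

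Genes called in the opposite direction to DSS numbered 4 with Kuiyangling and 18 with mesalazine without a filter, 5 and 17 with DESeq2 and 11 and 20 without both libraries, and 0 with any 1 library left out. The treatments shared 7, 9 and 19 genes in these 3 settings. Covariance beyond the part estimated for the shared libraries ran from -0.0883 to 0.0451 for Kuiyangling and -0.125 to 0.172 for mesalazine without 1 library, and was -0.187 for mesalazine without both. With the model libraries split between the changes it was -0.137 and -0.0174 for Kuiyangling and -0.0681 and 0.0959 for mesalazine, model 1 in the DSS change given before model 2.

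Among 2649 values of named genes, 36 turned sign, each in a gene uncalled in both fits. Mesalazine against the model, without 1 library: Reg3g -1.63 to 1.23, Lcn2 -1.43 to 2.46, Muc2 -1.13 to 0.076, Slc26a3 -0.86 to 0.64. Slc26a3 ran from -0.047 to 0.87 with Kuiyangling. Between the treatments: S100a9 -1.89 to 0.031, Cxcl1 -0.41 to 0.50, Il6 -0.71 to 0.13, Lcn2 -3.35 to 0.61, Reg3g -2.70 to 0.15, Muc2 -0.65 to 0.54, Slc26a3 -0.16 to 1.36, Car1 -0.28 to 0.20. Without both libraries, Reg3g was -1.62 and Lcn2 -1.40 for mesalazine against the model, Slc26a3 0.061 for mesalazine against control, and between treatments S100a9 0.037, Cxcl1 0.51, Lcn2 0.61, Reg3g 0.16, Muc2 0.55 and Slc26a3 -0.14. By limma, Reg3g (-0.21) and Slc26a3 (-0.13) for mesalazine against the model and Cxcl1 (0.12), Muc2 (0.10) and Car1 (0.14) between treatments had the other sign, as had Reg3g (-0.059) and Slc26a3 (-0.12) with the block. With length correction Reg3g was -0.092 for mesalazine against the model, and Cxcl1 0.40, Il6 0.10 and Car1 0.17 between treatments.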

Other observations

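The tests of time of day and of both explanations for control 2 were chosen only after the results were seen, and the genes named here were chosen after their values were seen.

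Clock output genes were higher in both treated groups than in the model. Dbp, a transcription factor whose transcript cycles daily, stood at 37.5 and 26.1 CPM with Kuiyangling and 32.3 and 31.9 with mesalazine, against 6.98 and 9.41 in the model and 2.87 and 2.90 in controls. Against controls it rose by 3.46 with Kuiyangling and 3.47 with mesalazine (adjusted p = 0.00742 and 0.00936), and Ciart, a clock repressor, by 3.23 and 3.25 (0.0429 and 0.0312). With mesalazine Tef rose by 1.75 and Arntl, of the opposite phase, changed by -2.19 (0.0334 and 0.0312). Against the model, 8 of 8 output genes had higher estimates with either treatment (medians 1.39 with Kuiyangling and 1.33 with mesalazine). The 5 opposite-phase genes were lower by estimate in 4 (median -0.29) and 3 (-0.19), and edgeR called 0 of 13 clock genes. Between the DSS model and controls, 5 of 8 output genes were higher by estimate (median 0.09). Of the 5 opposite-phase genes 4 were lower there (median -0.81), and 0 clock genes were called.

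The output minus opposite-phase difference, treated minus model, was 1.92 after the gene length trend was removed, which argues against a length effect. Collection at another time of day may give the same pattern (1.89 before that correction), and cannot be told apart from an effect of the treatments, since hours of collection were not used here and the treated animals differ from the model by treatment too.

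Mesalazine 1 stood apart from the other libraries. The other mesalazine animal had the same treatment, and a difference between the animals themselves was not tested. Lcn2 (58.4 against 3.97 CPM), Reg3g (8502 against 1177) and S100a9 (10.9 against 2.86) were higher in mesalazine 1 than in mesalazine 2. Cxcl2 (3.26 against 2.80) and Tnf (3.61 against 2.63) differed less, and Tlr4 (23.1 against 43.5) was lower. A few genes taking most of the counts is argued against: its 10 leading genes held 1.23 times the highest share elsewhere, below the limit of 1.5 set beforehand. At 11.8% of counts this share was still the highest of the 8 libraries, and the test does not cover shifts over many genes. Gene length bias may contribute, with rho = -0.534, lowest of the 8 libraries. With the trend removed its mean correlation rose from 0.940 to 0.957, no longer the lowest only because control 2 was at 0.951, while the other 6 were at 0.9698 or higher.

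Control 2 stood apart in B cell, MHC class II and posterior Hox genes, among others, a difference within a group, for which the design gives no biological explanation to test. The B and plasma cell markers had a median log2 ratio of 2.22 over control 1, with 12 of 13 higher, Cd74 at 1104 against 53.8 CPM and H2-Ab1 at 413 against 22.6. Lymphoid tissue in the sample may give this, but these genes are the pattern itself, so that their ratio decides nothing. T and NK cell markers (117 against 30.3 summed CPM) and interferon-stimulated genes (11013 against 4960) were higher in control 2 as well, values not held to any limit set beforehand, and the explanation stays open. A more distal piece of colon may also be involved, with a median of 0.96 over 3 posterior Hox genes, 2 of them higher, and -1.48 over 13 anterior ones, but 3 genes are too few to decide.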
